A study of Mus musculus with 18 samples.

How the data were processed

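RNA was measured in 18 libraries of mouse embryoid bodies, in 6 groups of 3 (control, knockout, and knockout with inhibitor, for the Mettl14 and the Mettl3 line). Per the labels' protocols, C57BL/6 embryonic stem cells kept in LIF with CHIR99021 and PD0325901 were grown for 7 days without feeders in embryoid body medium on ultra-low-attachment plates, with DMSO or 5 µM inhibitor. RNA was taken with Trizol, poly(A) RNA was selected with oligo(dT) beads, and libraries were made with the SMARTer Stranded Total RNA-Seq v2 kit, per the labels' protocols. Reads were called with CASAVA, trimmed with Trimmomatic 0.38, aligned to mm10 with HISAT2 2.1.0 and counted per gene with HTSeq, per the submitters' processing notes. The deposited values are raw counts per gene, per the labels, with 54446 gene identifiers in each file. The annotation release and the strand setting of the counting are not given in the sources used here; 54409 identifiers matched GENCODE mouse release M21 once the version was dropped, 37 did not, and symbols and coordinates come from that release.

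Everything else was computed here from the counts. Groups came from the labels. The comparisons, tests, the other settings listed below as such, the 42 gene lists and the rule for naming genes were fixed before the data were examined. Each line's 9 libraries were fitted together with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM size factors, quasi-likelihood F test), and the difference of the knockout effects was fitted on all 18. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. CPM of genes are TMM-scaled and given as mean ± SD of 3 libraries, except levels over many libraries and bounds, which use plain CPM; log2 fold changes carry the SE. The gene lists were tested with camera (limma 3.58.1, preset correlation 0.01, prior count 2), with p-values adjusted over the lists of a comparison, and again with an estimated correlation. Counts of genes adjusted over the list alone use the same p-values adjusted within the list.

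Named genes are the knocked-out gene, up to 6 called protein-coding genes with the largest rises and falls at 10 CPM or more in the higher group with no overlap between groups, up to 4 members with the smallest p of each list described, and Ezh2, Ezh1, Kdm6a and Kdm6b. Some genes that the rule names are not reported here, though counts and list tests include them. Genes outside this rule are said to have been named after their values were seen. Where a group had no count, the change is a bound from a floor of 3 counts per library. Depth set that floor between 0.0922 and 4.16 CPM, and the fits had a biological coefficient of variation of 0.394 (Mettl14 line), 0.843 (Mettl3 line) and 0.664 (all). By group it was 0.246 to 0.343, and 0.512 with GSK-J4. Intervals and floors cover counting error only.

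The other settings fixed at that stage were DESeq2 1.42.0, RLE size factors, no low-count filter, a replicate block, a log2 change of at least 1, only the 2 groups compared, all 18 libraries fitted, an estimated correlation and leaving out each library. After the data were seen, limma voom with quality weights, libraries thinned to the lowest total of each fit (721853, or 3395675 in the Mettl3 line) and the omission of the 2 shallowest libraries were added. The tests were tried on simulated data with changes of known size, and shared libraries were allowed for with 20 simulations per line. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.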

Results

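The series measured mRNA by sequencing in mouse embryoid bodies, the aggregates that embryonic stem cells form when they are left to differentiate in suspension. The stem cells were of the C57BL/6 strain and carried a conditional knockout (CKO) of Mettl14 or of Mettl3, which encode the paired subunits of the enzyme complex that places N6-methyladenosine (m6A) on mRNA. Each line gave 3 groups of 3 libraries, a control, the knockout and the knockout with an inhibitor at 5 µM, which makes 6 groups and 18 libraries after 7 days of differentiation. The inhibitor was GSK343 in the Mettl14 line, which blocks EZH2, the methyltransferase that places the repressive mark H3K27me3. In the Mettl3 line it was GSK-J4, which blocks the H3K27 demethylases KDM6A and KDM6B. The series design asks how a methyltransferase inhibitor affects the expression changes of the Mettl14 knockout, and its title treats METTL14 as a chromatin regulator apart from m6A. Nothing in the labels states that the replicates were separate cultures, so each p-value measures only the spread between these samples, which may be technical.

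Total counts ran from 8288902 to 10285737 in the Mettl14 controls, from 1303697 to 8688596 in the Mettl14 knockout and from 721853 to 20714764 with GSK343. In the Mettl3 line they ran from 21615674 to 29496824 in the controls, from 17544904 to 32540164 in the knockout and from 3395675 to 8289423 with GSK-J4. Genes of matrix-producing cells were abundant. In the 15 libraries without GSK-J4, Spp1 (osteopontin) had a median of 16802 CPM (counts scaled to library size) and Fn1 (fibronectin) 6806. Col1a1 (type I collagen) had 5789, Sparc 3226 and Vim (vimentin) 2103. The stem cell genes Pou5f1 and Nanog and the lineage genes Afp, Ttr, T and Cdx2 each had a median of 0 CPM over the 18 libraries. Xist, the RNA of the inactive X chromosome, and the summed Y-linked genes were both present in all 18 libraries, at 123 to 326 CPM and at 61.5 to 214 CPM. The GSK-J4 libraries stood apart from the rest. Mitochondrial mRNA made up 0.174 ± 0.0666% of their counts (SD, n = 3), against group means of 2.12 to 2.98% elsewhere. In 10 predicted genes of satellite-like repeat sequence they had 0.408 to 1.01% of their counts, against at most 0.0637% in each of the other 15 libraries. Spearman correlations between their replicates were 0.801 to 0.834, against 0.898 to 0.973 within the other groups. Knockout replicate 3 of the Mettl14 line had 7.57% of its counts in genes that overlap ribosomal RNA sequence.

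Loss of Mettl14 was compared with its control first. Mettl14 (ENSMUSG00000028114.16, chromosome 3, 123368297 to 123386108) had 16.4, 17.8 and 16.5 CPM in the controls, 16.3, 22.9 and 19.3 in the knockout, and 11.7, 16.7 and 12.5 with GSK343. Its log2 fold change in the knockout was 0.21 ± 0.37 (SE, n = 3 per group; adjusted p = 1.00 by edgeR). Counts over the whole gene may lie outside the deleted part, so they check neither the presence nor the absence of the deletion. Genes of cholesterol synthesis rose as a group, with a median log2 fold change of 0.54 and all 22 measured members positive. Squalene synthase (Fdft1) had 261 ± 15.7 CPM against 172 ± 5.89 (SD), and the sterol desaturase Sc5d 79.5 ± 10.4 against 50.5 ± 5.99, in each case with the 3 knockout libraries above the 3 controls. Neither gene passed alone, both with an adjusted p of 1.00 (edgeR quasi-likelihood, Benjamini-Hochberg). The m6A and Polycomb lists did not pass. Camera gave adjusted p = 0.877 for the 18 genes of the m6A machinery and again for the 11 of Polycomb repressive complex 2 (PRC2). It gave 0.858 for the 20 of Polycomb repressive complex 1, and 0.613 for 31 developmental regulators known as PRC2 targets. After TMM scaling, the summed levels of these 4 lists, each over all its genes, overlapped between knockout and control. For the regulators they were 994 CPM (range 943 to 1080.3) against 1059 (1051 to 1070.4). In plain CPM only the m6A sum overlapped. The others were lower in the knockout without overlap. PRC2 had 578 to 597 against 606 to 683, complex 1 had 702 to 796 against 824 to 907, and the regulators 878 to 1018 against 1066 to 1103. A sum follows its most abundant members, and these sums were not tested. Ezh2 changed by -0.10 ± 0.49 and Kdm6b by 0.01 ± 0.31 on the log2 scale. When single libraries were left out, these ran from -0.44 to 0.12 and from -0.54 to 0.22.

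**Figure D1:**
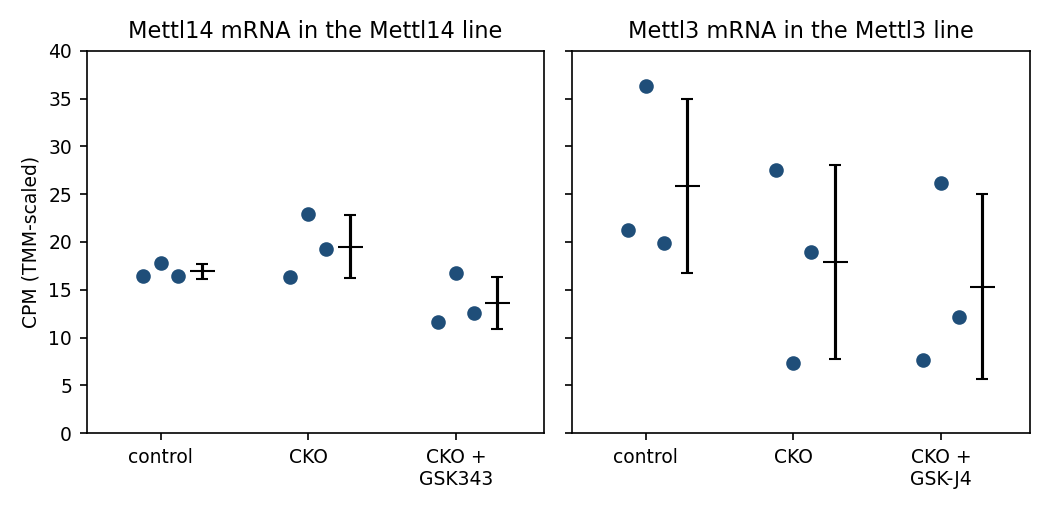
Mettl14 mRNA in the Mettl14 line and Mettl3 mRNA in the Mettl3 line, in CPM, with a point per library and the mean ± SD of 3 libraries beside the points. The knockout groups overlap their controls, at 19.5 ± 3.30 against 16.9 ± 0.803 CPM for Mettl14 and 17.9 ± 10.1 against 25.8 ± 9.13 for Mettl3.

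No gene of 13882 passed an adjusted p of 0.05 between the Mettl14 knockout and its control by edgeR, with 208 at an unadjusted p under 0.05 where 694 would arise by chance. DESeq2 and limma voom with quality weights also called 0, and edgeR without the low-count filter called 15. Leaving out knockout replicate 1 gave 7 calls and leaving out knockout replicate 2 gave 1. Named after their values were seen, the 7 were Gm23935, Gm26917, Gm42418 and Lars2, which overlap ribosomal RNA sequence, and the short noncoding genes Rprl3, Rn7sk and Gm24270, and the 1 was Rprl3. All 7 were among the 15 called without the filter, and knockout replicate 3, with 7.57% of counts in such overlapping genes, was in each of these fits. With changes of known size in simulated counts of the same gene-wise spread, the test recovered 73% of 4-fold and 10% of 2-fold changes. Changes of 2-fold or less were thus mostly not detectable in them. The simulated libraries were independent, while the real test found fewer genes at an unadjusted p under 0.05 than chance gives. Its recovery of real changes may therefore be different. RNA of cells without the deletion, if present, would also hide changes, which was not tested. The call of the cholesterol list (camera adjusted p = 7.34e-14) held without each library in turn, with medians of 0.38 to 0.55, and with an estimated correlation (adjusted p = 0.0467). Of the 41 lists tested, 4 others passed with the preset correlation and lost their call with an estimated one. Interferon response genes had a median of 0.77 (adjusted p = 0.0115, and adjusted p = 0.781 with an estimated correlation), with 1 gene higher adjusted over the list alone. Immediate early genes had a median of -0.26 (adjusted p = 0.0115, and 0.651 with an estimated correlation). Mesenchyme genes had a median of -0.23 (adjusted p = 0.0239, and 0.651 with an estimated correlation), with 1 gene lower adjusted over the list alone, and Col6a2 among them at 195 ± 24.8 against 348 ± 26.4 CPM. Cytosolic ribosomal protein genes had a median of 0.40 (adjusted p = 2.93e-06, and 0.781 with an estimated correlation), which became -0.08 without knockout replicate 1 (adjusted p = 0.998), 0.64 without control replicate 3 and 0.63 without knockout replicate 3. The interferon call was lost without control replicate 1, control replicate 3 or knockout replicate 2 (adjusted p 0.0949 to 0.661), with a median of 0.41 without knockout replicate 2 and 1.62 without control replicate 2, and the immediate early call without control replicate 2, control replicate 3 or knockout replicate 2 (0.120 to 0.244), with a median of -0.42 without control replicate 1. The mesenchyme call was lost without any of the 3 controls, knockout replicate 1 or knockout replicate 2 (0.0571 to 0.523).

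The effect of GSK343 on Mettl14 knockout cells is the question that the series design names. Mettl14 itself had 13.6 ± 2.71 CPM against 19.5 ± 3.30 without the inhibitor (log2 fold change -0.50 ± 0.38, SE). Cholesterol synthesis genes rose further, with a median log2 fold change of 0.97 and all 22 members positive. Lss (lanosterol synthase) rose to 170.1 ± 47.0 from 49.7 ± 17.3 CPM (log2 fold change 1.75 ± 0.30, adjusted p = 0.0498 by edgeR quasi-likelihood with Benjamini-Hochberg). Crabp1, a retinoic acid binding protein, rose to 77.5 ± 29.1 from 7.56 ± 5.85 CPM (3.11 ± 0.53), and Cryab, a small heat shock protein, to 165 ± 64.3 from 35.6 ± 14.9 CPM (2.18 ± 0.38), each with an adjusted p of 0.0498. These 3 genes lie on chromosome 10 (Lss, ENSMUSG00000033105.12) and chromosome 9 (Crabp1, ENSMUSG00000032291.8, and Cryab, ENSMUSG00000032060.10). In each of them the treated and untreated libraries did not overlap, which the rule for naming the largest rises requires, so it adds no support.

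Immediate early genes, which answer to growth signals within minutes, had a median of 0.41 (camera adjusted p = 0.000235, and 0.605 with an estimated correlation), with 3 of 15 higher adjusted over the list alone. Fos had 35.5 ± 12.6 against 8.44 ± 3.99 CPM, with an adjusted p of 0.128 over all genes (edgeR). This list's call held without each library in turn. The call of the cholesterol list held so too (adjusted p = 1.69e-21, and 0.0145 with an estimated correlation). Adjusted over the list alone, 19 of the 22 cholesterol genes were higher. The lists of known Polycomb targets did not pass. Their tested members are those past the low-count filter, and they do not single out genes silent without the inhibitor. A release of silent genes by GSK343 was therefore not tested separately. The 31 tested regulators had a median of 0.16 (camera adjusted p = 0.234), the HOXA genes 0.07 (0.968), the HOXB genes -0.09 (0.906), the HOXC genes -0.10 (0.982) and the HOXD genes 0.36 (0.305). The summed level of all 50 listed regulators was higher without overlap, at 1105 CPM (range 1085 to 1129.8) against 994 (943 to 1080.3), with the controls at 1059. The PRC2 sum was lower without overlap, at 528 (514 to 546) against 619.7 (595 to 651), and that of complex 1 overlapped. These sums were not tested. Ezh2 itself changed by -0.19 ± 0.50 on the log2 scale, and by -0.75 to 0.14 when single libraries were left out.

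In all, edgeR called 4 of 13882 genes (4 higher, 0 lower, 797 at an unadjusted p under 0.05), close to the threshold. Lss, Crabp1 and Cryab lost their call without knockout replicate 2, knockout replicate 3, GSK343 replicate 1 or GSK343 replicate 3, with adjusted p from 0.0739 to 0.260. The number called was 0 without any of the first 3 and 14 without knockout replicate 1. The sizes moved less, as Lss stayed between 1.52 and 2.11 and Crabp1 between 2.80 and 3.43. DESeq2 called 57 genes and limma voom with quality weights 19, while edgeR called 0 with libraries thinned to an equal depth and 2 without the pair of shallowest libraries. In simulated counts with 200 changed genes, 27 of 111 DESeq2 calls were false, a share that need not hold for the real calls.

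Against the control, in a comparison that shares the treated libraries with the one above, 15 of the 22 cholesterol genes rose (median 1.47, camera adjusted p = 2.08e-43, and 0.00199 with an estimated correlation), with 20 higher adjusted over the list alone. Lss rose by 2.07 ± 0.30 on the log2 scale, Sc5d by 1.74 ± 0.24 and Insig1, a sterol sensor of the pathway, by 1.70 ± 0.22. These 3 kept their calls without each library in turn. Acat2, Fdft1, Idi1 and Hmgcs1 of the same pathway rose by 1.27 to 2.07. The other 6 genes that rose were Crabp1, Cryab and, named after their values were seen, Elovl6 (1.95 ± 0.28) and Scd1 (1.48 ± 0.28) of fatty acid synthesis and Hsd17b7 (1.57 ± 0.25) and Tm7sf2 (2.00 ± 0.40) of sterol synthesis. The 2 genes that fell, also named after their values were seen, were Abcg1, a cholesterol exporter, at 21.1 ± 10.7 against 66.2 ± 4.68 CPM, and the endothelin receptor gene Ednra, at 20.1 ± 4.31 against 53.6 ± 4.03 CPM.

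In all, edgeR called 23 of 13882 genes against the control (21 higher, 2 lower, 602 at an unadjusted p under 0.05), DESeq2 68 and limma voom with quality weights 65. Leaving out control replicate 1, 2 or 3 gave 7, 4 and 13 calls and leaving out GSK343 replicate 1 or 2 gave 4 and 9. Each of the 12 genes named here other than Lss, Sc5d and Insig1 lost its call without control replicate 2 or GSK343 replicate 1. Calls were also lost without control replicate 1 for all of these but Elovl6, Idi1 and Hsd17b7, without GSK343 replicate 2 for all but Elovl6 and Cryab, without control replicate 3 for Idi1, Hmgcs1, Abcg1, Ednra, Scd1 and Hsd17b7, and without GSK343 replicate 3 for Crabp1, Cryab and Tm7sf2 (adjusted p 0.0514 to 0.336). Mesenchyme genes had a median of -0.54 (adjusted p = 0.00257, and 0.302 with an estimated correlation), with 6 lower and 1 higher adjusted over the list alone, and lost their call without control replicate 2, GSK343 replicate 1 or GSK343 replicate 2 (0.0636 to 0.204). Genes of the ATF4 stress response had a median of 0.28 (adjusted p = 0.0141, and 0.282 with an estimated correlation), lost without any library but control replicate 3 (0.0563 to 0.0967), at 0.17 without control replicate 1 and 0.12 without GSK343 replicate 3. Ribosomal protein genes had a median of 0.20 (adjusted p = 0.0117, and 0.942 with an estimated correlation), which was 0.01 without GSK343 replicate 3, 0.08 and 0.09 without control replicates 1 and 2 (adjusted p 0.194 to 0.877) and 0.41 without control replicate 3.

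**Figure D2:**
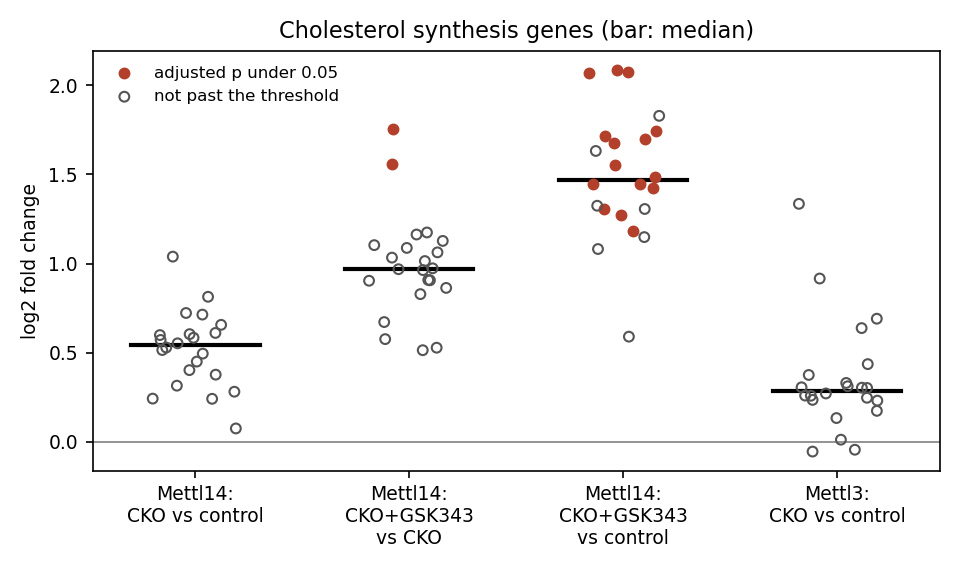
Log2 fold change of the 22 cholesterol synthesis genes in 4 comparisons, with a point per gene, filled where the edgeR adjusted p is under 0.05, and a bar at the median. The medians are 0.54 for the Mettl14 knockout against its control, 0.97 for GSK343 against the knockout, 1.47 for GSK343 against the control and 0.29 for the Mettl3 knockout against its control.

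Whether GSK343 undoes the changes of the Mettl14 knockout was asked gene by gene. In neither line was a control given an inhibitor. An effect on the knockout's changes thus cannot be told from one that the controls would show too. No gene was called in the knockout and called in the opposite direction with GSK343, since the knockout gave 0 calls by edgeR, DESeq2 and limma voom with quality weights, with 208 genes at an unadjusted p under 0.05. The cholesterol genes moved the same way in both steps. Across 9021 genes, which are not independent replicates, the covariance of the knockout and inhibitor log2 changes was -0.0637, and counts simulated with no inhibitor effect gave -0.0590 ± 0.00290 (SD of 20 simulations), because both steps share the knockout libraries. The Pearson correlation was -0.513 against -0.326 ± 0.0140 in the simulations, and 68.0% of genes had opposite signs against 61.7 ± 0.704%. The simulated counts were drawn around the observed group means, which already hold sampling error. That widens the simulated knockout changes and weakens their correlation and share of opposite signs, so these values do not by themselves show reversal. From mean log2 levels the covariance was -0.0662, where the spread of the shared knockout libraries alone gives -0.0909. It was -0.127 without knockout replicate 1 (-0.126 from that spread) and -0.121 without knockout replicate 2 (-0.202).

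Loss of Mettl3 was then compared with its control. Mettl3 (ENSMUSG00000022160.18, chromosome 14, 52294841 to 52305128) had 21.3, 36.3 and 19.9 CPM in the controls, 27.5, 7.29 and 18.96 in the knockout, and 7.68, 26.2 and 12.1 with GSK-J4, so that the groups overlapped. Its log2 fold change in the knockout was -0.53 ± 0.63 (SE; adjusted p = 1.00 by edgeR), and the same limit on whole-gene counts applies. Neural crest genes had a median log2 fold change of 0.46 with 9 of 11 positive (camera adjusted p = 0.000119, and 0.365 with an estimated correlation), among them the nerve growth factor receptor Ngfr at 122 ± 24.3 against 32.4 ± 41.6 CPM and the transcription factor gene Snai2 at 188 ± 33.6 against 137 ± 25.4. The log2 fold change of Ngfr, 1.92 with all libraries, was 3.85 without control replicate 3, and that of Snai2, 0.46, was 0.30 without knockout replicate 2. Ribosomal protein genes had a median of -0.42 with all 30 negative (adjusted p = 5.91e-10, and 0.590 with an estimated correlation), as Rps3 had 615 ± 118 against 836 ± 127 CPM. Genes of hypoxia and glycolysis had a median of -0.32 (adjusted p = 0.0136, and 0.365 with an estimated correlation), the glucose transporter gene Slc2a1 having 121 ± 9.68 against 166 ± 6.82 CPM.

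No single gene passed. By edgeR, 0 of 16782 genes were called, with 315 at an unadjusted p under 0.05 and 839 expected by chance, while DESeq2 called 32, limma voom with quality weights 6 and edgeR on these 2 groups alone 2. The edgeR fit shares its spread with the variable GSK-J4 libraries, and in simulated counts it recovered 17% of 4-fold and 0% of 2-fold changes here, against 61% and 24% with the 2 groups alone. The limits of independent simulated libraries and of any cells without the deletion apply here too. The camera calls of the neural crest and ribosomal lists held without each library in turn, the ribosomal median being -0.27 without control replicate 2 and -0.26 without knockout replicate 3. None of the 6 lists that passed did so with an estimated correlation. The other 4 were hypoxia and glycolysis, cholesterol synthesis (median 0.29, adjusted p = 0.0136), Wnt targets (median 0.28, adjusted p = 0.0479) and definitive endoderm (median -1.44, adjusted p = 0.0310), each at 0.365 with an estimated correlation. Those 4 lost their call without 4 or 5 of the 6 libraries, namely control replicate 2 and knockout replicates 1 and 2, control replicate 1 for all but hypoxia, knockout replicate 3 for all but cholesterol, and control replicate 3 for hypoxia (adjusted p 0.0586 to 0.472). The median of the 5 definitive endoderm genes was 0.25 without control replicate 1, -2.43 without knockout replicate 1 and -0.77 without knockout replicate 2. That of the Wnt targets was 0.15, 0.44 and 0.12 without control replicate 2, control replicate 3 and knockout replicate 3, and that of hypoxia -0.21 without control replicate 2.

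GSK-J4 was then compared with the untreated Mettl3 knockout, in which Mettl3 had 15.3 ± 9.67 against 17.9 ± 10.1 CPM (log2 fold change -0.22 ± 0.63). Nkd2 and Sfrp2, which restrain Wnt signalling, were without a count in the treated libraries and stood at 109.9 and 72.3 CPM in the untreated ones, at least 177-fold and 116-fold lower. Aspn (asporin, a matrix proteoglycan) was at least 113-fold lower, Eml1 109-fold, Lrrc15 94.2-fold and Npy (neuropeptide Y) 82.8-fold, each bound taken against a floor of 3 counts per library, which covers counting error only. Of 20 mesenchyme genes 18 fell, with a median of -3.56 (camera adjusted p = 3.35e-08, and 0.0756 with an estimated correlation), and type I collagen fell from 6799 ± 513 to 159 ± 75.1 CPM for Col1a1 and from 3681 ± 353 to 86.1 ± 47.5 for Col1a2. Col6a3 fell by 4.62 ± 0.46 and Col5a1 by 3.23 ± 0.37 on the log2 scale. Fibronectin (Fn1) had a log2 fold change of -0.57 ± 0.29 (adjusted p = 0.217 by edgeR, and -1.01 with adjusted p = 0.0134 without GSK-J4 replicate 2). Among 12 markers of parietal endoderm, a basement membrane secreting tissue, 6 fell (median -1.36, camera adjusted p = 0.00336, and 0.139 with an estimated correlation), led by Sparc (-3.69 ± 0.28) and the type IV collagens Col4a1 (-2.53 ± 0.21) and Col4a2 (-3.13 ± 0.24).

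Of 13 messenger RNAs encoded by the mitochondrial genome 9 fell and 1 rose, with a median of -4.39 (adjusted p = 2.89e-06, and 0.139 with an estimated correlation), as mt-Co1 (cytochrome oxidase) went from 7156 ± 691 to 245 ± 89.3 CPM and mt-Cytb from 4562 ± 396 to 113 ± 52.5. The gene that rose was mt-Nd6, the mRNA read from the other strand, at 564 ± 118 against 190.1 ± 36.1 CPM. Of 22 cholesterol synthesis genes, which had risen with GSK343 in the other line, 13 fell (17 adjusted over the list alone; median -1.61, camera adjusted p = 5.52e-06, and 0.0756 with an estimated correlation), and Srebf2, a transcription factor gene that drives the pathway, went from 179 ± 14.6 to 66.8 ± 8.57 CPM. The difference between the inhibitors was not tested, since they were used in different lines. Of 11 Wnt targets 4 fell (6 adjusted over the list alone; median -1.78, camera adjusted p = 0.00105, and 0.0756 with an estimated correlation), Ccnd1 (cyclin D1) from 184 ± 13.2 to 61.2 ± 24.4 CPM and Tcf7, Dkk1 and Rnf43 to 0 counts, at least 18.9-fold, 4.80-fold and 3.86-fold lower.

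Of 20 targets of the tumour suppressor p53, 8 rose (14 adjusted over the list alone; median 0.84, camera adjusted p = 1.58e-05, and 0.0506 with an estimated correlation), with Mdm2, its negative regulator, at 1524 ± 326 against 404 ± 44.5 CPM, and Pmaip1, Trp53inp1 and Phlda3 higher by 1.09 to 1.23 on the log2 scale. Of 19 genes of hypoxia and glycolysis 8 rose (11 higher and 1 lower adjusted over the list alone; median 0.85, camera adjusted p = 4.75e-05, and 0.0871 with an estimated correlation), among them the glucose transporters Slc2a1 (1.13 ± 0.17) and Slc2a3 (2.62 ± 0.45), Eno1 (1.00 ± 0.16) and the mitophagy gene Bnip3 (1.87 ± 0.32). Of 17 replication-dependent histone genes 6 rose (9 adjusted over the list alone; median 2.02, camera adjusted p = 3.52e-08, and 0.0506 with an estimated correlation), with Hist1h4c at 38.2 ± 20.4 against 0.391 ± 0.421 CPM and Hist1h2ac and Hist1h4d higher by 3.28 ± 0.63 and 3.45 ± 0.68. Histone mRNAs carry no ordinary poly(A) tail. In the ATF4 list 5 genes rose and 3 fell, and its median (0.05), its mean (-0.29) and its test (higher, adjusted p = 0.598) differed in sign. Ddit3, Atf4 and the cystine transporter gene Slc7a11 rose by 1.84 ± 0.22, 1.32 ± 0.20 and 2.62 ± 0.46, while Aldh1l2 of mitochondrial folate metabolism fell by 3.68 ± 0.27.

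The largest rises were of genes nearly silent without the inhibitor. For genes that rose from below 1 CPM, background reads from the genome could not be excluded, as set out below. Aoc3 had no count in the untreated libraries and was at least 95.1-fold higher. Lsr, Myo3a, Hist1h4b and Olfr720 had 1 or 2 counts over the 3 untreated libraries, and the ratio of pooled CPM was 1473 for Lsr (95% interval 262 to 58347, exact conditional binomial, counting error only), 1195 for Myo3a (213 to 47395), 1300.4 for Hist1h4b (231 to 51549) and 643 for Olfr720 (176 to 5337). The cytokine gene Cxcl1 had 729 ± 1216 against 1.12 ± 1.58 CPM. Among chromatin and RNA methylation genes, 3 of 11 PRC2 genes rose (median 0.90, camera adjusted p = 0.0344, and 0.139 with an estimated correlation), Suz12 by 1.48 ± 0.30, Eed by 1.24 ± 0.29 and Aebp2 by 0.90 ± 0.24. Of 18 m6A genes 3 rose (median 0.37, adjusted p = 0.0274, and 0.139 with an estimated correlation), the reader Ythdc1 by 1.89 ± 0.19, Zc3h13 by 1.05 ± 0.24 and the demethylase Alkbh5 by 1.06 ± 0.31. Ezh2 had a log2 fold change of 1.12 ± 0.57 (adjusted p = 0.222, and 0.0388 without GSK-J4 replicate 3), Kdm6a -0.05 ± 0.41 and Kdm6b 0.04 ± 0.28. Of 35 tested regulators on the list of PRC2 targets 7 fell and 0 rose (median -0.80, camera adjusted p = 0.0624, and 0.139 with an estimated correlation). The cell cycle inhibitor Cdkn2a was down by 2.00 ± 0.24 and Wnt5a by 2.68 ± 0.33, and Dlx5 and Wnt10b were at 0 counts, at least 14.3-fold and 7.42-fold lower. Of 25 imprinted genes 2 rose and 5 fell (median 0.16, mean -0.11, test lower with adjusted p = 0.956), with the noncoding H19, Rian and Meg3 falling by 4.98 ± 0.33, 2.38 ± 0.24 and 2.32 ± 0.34. Of 6 surface epithelium genes 2 rose (median 2.43, camera adjusted p = 0.0232, and 0.139 with an estimated correlation), Perp by 1.57 ± 0.33 and the tight junction gene Cldn4 by 6.26 ± 1.64.

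**Figure D3:**
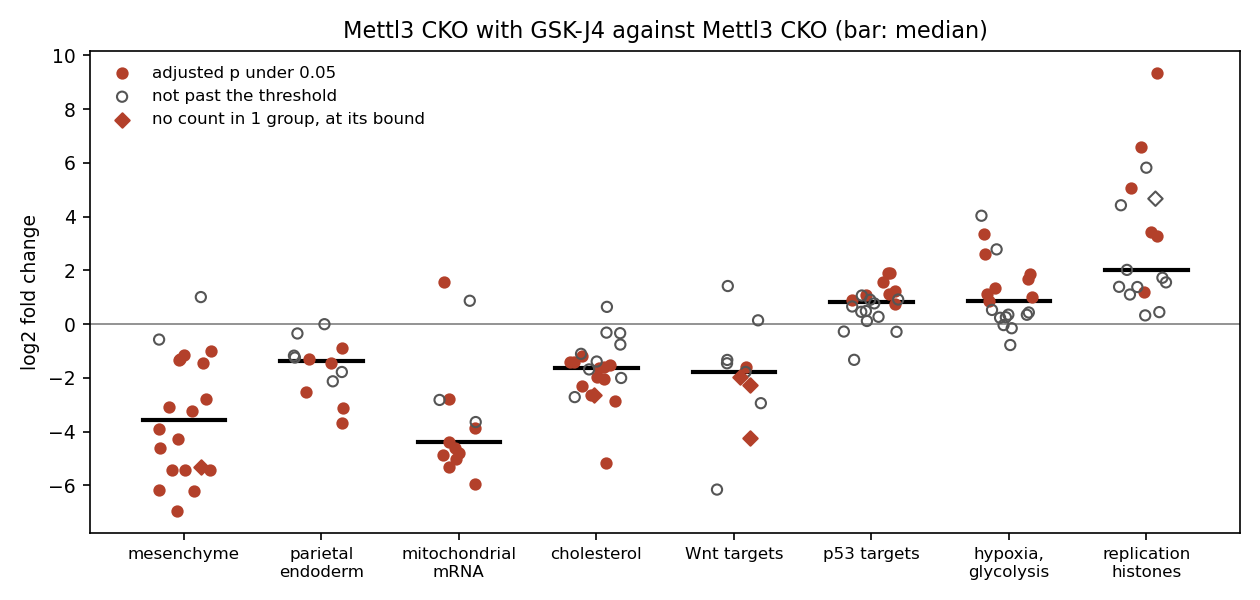
Log2 fold change of the members of 8 gene lists between the Mettl3 knockout with GSK-J4 and without it, with a point per gene, filled where the edgeR adjusted p is under 0.05, a diamond where a group had no count and the value is a bound, and a bar at the median. The medians run from -4.39 for mitochondrial mRNA and -3.56 for mesenchyme genes to 2.02 for histone genes.

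In all, edgeR called 2186 of 16782 genes with GSK-J4 (664 higher, 1522 lower; 1905 with a log2 change of at least 1). Limma voom with quality weights called 1734, of which 1423 were shared, all in the same direction. Its count is given because, in simulated counts with the wider spread of the GSK-J4 libraries, 74 of 104 edgeR calls were false against 2 of 18 with voom. Only 200 of the 16782 simulated genes were changed, so these shares are not estimates for the real calls. Of the 12 genes with the largest changes, Aspn and Cxcl1 were not called by voom (adjusted p = 0.0533 and 0.124). Leaving out knockout replicate 1, 2 or 3 gave 1032, 1113 and 1060 calls. Of 42 lists, camera called 11, and none of these passed with an estimated correlation (adjusted p 0.0506 to 0.139).

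Single libraries decided part of these calls. The m6A and PRC2 lists lost theirs without any 1 of the 6 libraries (adjusted p 0.0506 to 0.141 and 0.0660 to 0.135), and the Wnt and surface epithelium lists without GSK-J4 replicate 2 (0.0921 and 0.0501). Medians moved to 0.32 and 0.56 for hypoxia without GSK-J4 replicate 1 and knockout replicate 2, to 3.73 for surface epithelium without knockout replicate 1, to -1.18 for Wnt without GSK-J4 replicate 2, to 0.24 and 0.21 for m6A without knockout replicate 2 and GSK-J4 replicate 1, and to 0.55 and 0.46 for PRC2 without GSK-J4 replicates 1 and 3. Aoc3, Myo3a, Olfr720, Eed, Aebp2, Alkbh5, Dkk1 and Rnf43 lost their calls without each of knockout replicates 1, 2 and 3. Aebp2 lost it also without GSK-J4 replicate 1, Alkbh5 without GSK-J4 replicate 3, Dkk1 without GSK-J4 replicates 2 and 3 and Rnf43 without all 3. Calls were also lost for Suz12 without knockout replicate 1 or 2, Zc3h13 without these or GSK-J4 replicate 3, Trp53inp1 without knockout replicate 2, Wnt10b without knockout replicate 1 or 3, Perp without knockout replicate 1, Cldn4 without knockout replicates 1 or 3 or GSK-J4 replicate 1, and Cxcl1 without knockout replicate 1 or 2 or GSK-J4 replicate 1, at adjusted p from 0.0513 to 0.217 for these genes. Sizes moved to 4.43 for Cxcl1 and 0.55 for Aebp2 without GSK-J4 replicate 1, and to 0.44 for Alkbh5 without GSK-J4 replicate 3. The collagens, Sparc, the mitochondrial, histone, cholesterol and ATF4 genes, Mdm2, Pmaip1, Phlda3, the 4 glycolysis genes, Lsr, Tcf7, Ccnd1, Ythdc1, Cdkn2a, Wnt5a, Dlx5, the 3 imprinted genes and the 6 largest falls kept theirs without each library in turn.

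The GSK-J4 group was also compared with the control, which is no independent test, since the 3 GSK-J4 libraries are shared with the comparison above. Camera called 12 lists, and none of them passed with an estimated correlation (the lowest adjusted p with an estimated correlation was 0.0514, for p53 and histones). Mesenchyme genes fell (17 of 20, median -3.54, camera adjusted p = 4.54e-08, and 0.115 with an estimated correlation) with Col1a1 down by 4.89 ± 0.32, as did mitochondrial mRNA (9 of 13, median -4.53, adjusted p = 9.03e-07, and 0.145 with an estimated correlation) with mt-Co1 down by 4.89 ± 0.26 and mt-Nd6 up by 1.35 ± 0.21. Of 22 cholesterol genes 10 fell (median -1.27, or -1.26 with genes at 0 counts set to their bound, camera adjusted p = 8.67e-05, and 0.115 with an estimated correlation). Of 11 Wnt targets 2 fell (median -2.24, or -1.30 at the bound, camera adjusted p = 0.00531, and 0.115 with an estimated correlation). Of 20 p53 targets 8 rose (median 0.70, camera adjusted p = 2.12e-05), with Mdm2 up by 1.93 ± 0.20, and of 17 histone genes 5 rose (median 2.48, camera adjusted p = 4.54e-08). Both lists had a camera adjusted p of 0.0514 with an estimated correlation. In this comparison Suz12 rose by 1.68 ± 0.30 and Ythdc1 by 1.79 ± 0.19, and Nkd2 was at least 121-fold lower. These single genes kept their calls without each library in turn. The remaining lists past the threshold were parietal endoderm, hypoxia, m6A, PRC2, surface epithelium and ribosomal genes (adjusted p 0.00235 to 0.0439, and 0.145 to 0.822 with an estimated correlation). The hypoxia call was lost without GSK-J4 replicate 1, the Wnt call without GSK-J4 replicate 2, and the ribosomal call without that library or control replicate 2. The m6A call was lost without control replicate 1 or 2 or GSK-J4 replicate 1 or 2, and the PRC2 and surface epithelium calls were lost without any 1 library (adjusted p 0.0501 to 0.217 for these lists). With RLE size factors the surface epithelium and ribosomal lists also lost theirs (adjusted p = 0.0593 for both). Medians moved to 0.11 and 0.23 for hypoxia without GSK-J4 replicate 1 and control replicate 1, to -1.49 for Wnt without GSK-J4 replicate 2, and, without GSK-J4 replicate 1, to 0.23 for m6A, 0.59 for PRC2 (0.54 without GSK-J4 replicate 3) and 1.54 for surface epithelium. By edgeR 1916 of 16782 genes were called (531 higher, 1385 lower) and by limma voom with quality weights 1683. Leaving out control replicate 1, 2 or 3 gave 1076, 980 and 888.

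Whether GSK-J4 undoes the changes of the Mettl3 knockout gave no called gene, since edgeR called 0 genes in the knockout (315 at an unadjusted p under 0.05), although DESeq2 gave 15 opposite genes and limma voom with quality weights 4. In simulated counts, 26 of 80 DESeq2 calls were false for the Mettl3 knockout and 1125 of 1203 for GSK-J4, against 10 of 82 and 2 of 18 with voom. These shares belong to simulations with 200 changed genes and are not estimates for the real calls. Across 9322 genes, which are not independent replicates, the covariance of the 2 steps was -0.149, against -0.0604 ± 0.00624 (SD of 20 simulations) in counts simulated with no inhibitor effect. The Pearson correlation was -0.269 against -0.120 ± 0.0102, and 60.2% of genes had opposite signs against 54.9 ± 0.373%. As in the Mettl14 line, the way the counts were drawn weakens the simulated correlation and share of opposite signs, though not the covariance. From mean log2 levels the covariance was -0.181, where the spread of the shared knockout libraries alone gives -0.0506. The simulations drew genes independently and held no inhibitor effect, so their SD leaves out a large effect shared by many genes. The covariance does not by itself show reversal either.

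The knockouts were last compared with each other. The difference of the Mettl14 and Mettl3 effects was below 0 for neural crest genes (median -0.78; camera adjusted p = 1.45e-05, and 0.0436 with an estimated correlation). It was above 0 for ribosomal protein genes (0.78; adjusted p = 1.50e-15, and 0.529 with an estimated correlation) and for hypoxia and glycolysis genes (0.39; adjusted p = 0.000528, and 0.0744 with an estimated correlation). No gene of 16326 was called for that difference by edgeR (366 at an unadjusted p under 0.05) or by limma voom with quality weights, while DESeq2 called 20. No gene changed in the same direction in both knockouts at an adjusted p of 0.05 by edgeR, DESeq2 or limma voom with quality weights. None could, since each of these called 0 genes in the Mettl14 knockout. At an unadjusted p under 0.05, 0 genes were higher in both where 0.488 would be shared by chance, and 3 were lower in both where 0.623 would be (Fisher's exact test, two-sided p = 0.0245). That test treats genes as independent replicates, which they are not, and its p-value rests on 3 genes. With the same limit, across 8685 genes the effects had a Pearson correlation of -0.189 and a Spearman correlation of -0.215, and 42.2% had the same sign. Cholesterol genes had positive medians in both knockouts, at 0.54 and 0.29, the call of the second being lost with an estimated correlation (adjusted p = 0.365 with an estimated correlation).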

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

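These lists were flagged because the Mettl14 and the Mettl3 knockout effects differ, by a test of the difference itself, and the lists were fixed before the data were examined. Neural crest genes had a median difference of -0.78 with all 10 below 0 (camera adjusted p = 1.45e-05, and 0.0436 with an estimated correlation). Hypoxia and glycolysis genes had a median difference of 0.39 (adjusted p = 0.000528, and 0.0744 with an estimated correlation), which was 0.24 without Mettl14 knockout replicate 1. Ribosomal protein genes had a median difference of 0.78 with all 30 above 0 (adjusted p = 1.50e-15, and 0.529 with an estimated correlation), which was 0.25 without Mettl14 knockout replicate 1. All 3 calls held without each of the 12 libraries in turn.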

How the results depend on the processing

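The lists of cholesterol synthesis in the Mettl14 line and the collagen, mitochondrial and Mdm2 changes with GSK-J4 kept their direction and their side of the threshold without each library in turn, while 51 counts of called genes moved with another choice and 121 did not; where they did, the cause was not tested. Limma voom with quality weights, equal depth and the omission of the 2 shallowest libraries were chosen after the results were seen. The lowest total of the Mettl14 line, 721853, limits what equal depth can detect there; in the Mettl3 line it was 3395675.

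For the Mettl14 knockout against its control (0 calls), no low-count filter gave 15, and leaving out a library 0 to 7. For GSK343 against the knockout (4 calls), DESeq2 gave 57, RLE size factors 1, no low-count filter 50, limma voom with quality weights 19, libraries thinned to the lowest total 0, without the 2 shallowest libraries 2, all 18 libraries fitted 0, and leaving out a library 0 to 14. For GSK343 against the control (23), DESeq2 gave 68, no low-count filter 63, limma voom with quality weights 65, without the 2 shallowest libraries 37, only the 2 groups compared 35, all 18 libraries fitted 2, and leaving out a library 4 to 28. For the Mettl3 knockout against its control (0), DESeq2 gave 32, no low-count filter 6, limma voom with quality weights 6 and only the 2 groups compared 2. For GSK-J4 against the knockout (2186), DESeq2 gave 4431, only the 2 groups compared 977, all 18 libraries fitted 3373 and leaving out a library 1032 to 3061. For GSK-J4 against the control (1916), DESeq2 gave 4360, only the 2 groups compared 887, all 18 libraries fitted 3155 and leaving out a library 888 to 2798. For the difference of the knockout effects (0), DESeq2 gave 20 and no low-count filter 13. Reversal of Mettl14 knockout changes (0) gave 10 genes with no low-count filter and 0 to 3 on leaving out a library; reversal of Mettl3 knockout changes (0) gave 15 with DESeq2, 3 with no low-count filter and 4 with limma voom with quality weights.

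The median of the ribosomal list in the Mettl14 knockout ran from -0.077 without knockout replicate 1 to 0.64 without control replicate 3, and that of the definitive endoderm list in the Mettl3 knockout from -2.43 without knockout replicate 1 to 0.25 without control replicate 1. Libraries of different groups share only a replicate number, and same-numbered libraries deviated from their group means with correlations of -0.287 to 0.242. That gives no sign of pairing by replicate number. In the Mettl14 line, knockout replicate 1 had 0.503 with control replicate 3 and -0.404 with control replicate 2. Structure shared between groups in another way, such as a batch, is therefore possible and was not tested. With a replicate block the calls numbered 1 for GSK343 against the knockout, 1407 for GSK-J4 against the knockout and 1256 for GSK-J4 against the control, and the mesenchyme list of the Mettl14 knockout had an adjusted p of 0.0527 and the Wnt list of the Mettl3 knockout 0.0728. The block moved the median of neural crest genes from -0.78 to -1.75 for the difference of the knockout effects, that of Wnt targets from -1.78 to -3.43 with GSK-J4 against the knockout, and that of hypoxia from 0.85 to 0.53 there and from 0.48 to 0.27 against the control.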

Other observations

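The genes of this paragraph were chosen after their values with GSK-J4 were seen, and no list of their kind was tested. In the Mettl3 knockout the metallothionein gene Mt1 went from 320 ± 57.4 to 7002 ± 1392 CPM (log2 fold change 4.45 ± 0.25, adjusted p = 3.28e-06 by edgeR), Mt2 rose by 5.41 ± 0.28 and the zinc exporter gene Slc30a1 by 2.92 ± 0.39. Of genes of haem and iron handling, Hmox1 rose by 2.19 ± 0.18, the transferrin receptor gene Tfrc by 2.38 ± 0.34 and the ferritin genes Fth1 by 1.18 ± 0.16 and Ftl1 by 0.95 ± 0.20. Among heat shock genes, Hsp90aa1 rose by 1.56 ± 0.22, Hspa1b by 4.78 ± 0.80 and Hspa1a by 4.33 ± 0.88, the last at 1.97 and Hspa1b at 3.05 without GSK-J4 replicate 1. Ftl1 lost its call without knockout replicate 2 or GSK-J4 replicate 3, and Hspa1a without knockout replicate 2 (adjusted p 0.0505 to 0.0589).

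Of the tests below, the length and expression test, the genomic background test and the splits of the libraries were written before their results were seen, and the others after.

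Genes of fibroblasts were abundant in the libraries without GSK-J4, with Spp1, Fn1 and Col1a1 at medians of 16802, 6806 and 5789 CPM. All RNA coming from 1 clonal stem cell line of ordinary karyotype is not what the sex-linked genes show, since Xist and the Y-linked genes were both above 3 counts in 18 of 18 libraries. RNA of growth-arrested feeder fibroblasts fits, as the median mitosis gene stood at 1.35 CPM and the cell cycle inhibitor Cdkn2a at a median of 156 CPM. The labels, however, describe culture without feeders. Embryoid bodies can also hold mesenchyme of their own, and the matrix genes alone do not separate the sources. The sex-linked genes argue against mesenchyme of 1 such clonal line as the only source. The share of each source was not measured. If such cells carry no deletion, they could also account for Mettl14 counts that were not lower and Mettl3 counts that overlapped those of the controls. The lack of called genes in both knockouts, and the inhibitor comparisons, would then say less about loss of Mettl14 or Mettl3. That was not tested.

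Mitochondrial and matrix genes were lower with GSK-J4, and 5 explanations were tested. Lower depth is not the reason, as 2028 of 2186 called genes were still called in the same direction in libraries of equal depth. Weaker selection for poly(A) tails cannot be told apart: Rn7sk, Rprl3, Malat1, mt-Rnr1 and mt-Rnr2, which lack an ordinary tail, had a median of -0.74, but the histone genes had 2.02 and mt-Nd6 rose by 1.57. Background reads diluting all genes would lower the rest as well, and 9179 other genes had a median of 0.0381, against -3.55 for mesenchyme and -4.38 for mitochondrial genes. Genomic background under the genes that rose from below 1 CPM cannot be told apart. Of 36 such genes 97.2% lay above the 95th percentile of 3654 silent genes, but a gene is called only when it has many reads. The bound written beforehand would thus be passed either way, and satellite-like genes held 0.408 to 1.01% of the counts with GSK-J4 against at most 0.0637% elsewhere. Loss of fibroblast-like cells would lower the RNAs of the mitochondrial genome alike. Its mRNAs had a median log2 fold change of -4.39, but mt-Rnr1 had -0.39 ± 0.28, mt-Rnr2 -0.74 ± 0.20 (SE) and mt-Nd6 1.57. These values argue against such a loss as the sole cause for the mitochondrial genes. They lie outside the bound of the test, which could not tell, and the same RNAs bear on poly(A) selection, left open above. For the matrix genes it could not be told apart, since 8 lists of other cell types had medians from -3.65 to 2.86 with wide spread.

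Cholesterol synthesis genes were higher with GSK343. The 2 shallowest libraries do not account for this, as the median without them was 0.95 (camera adjusted p = 1.72e-15), nor does gene length or expression level, as 0% of 10000 matched lists reached the list's 0.97 and the highest gave 0.27. An effect of EZH2 on the pathway and a direct effect of the compound on sterol handling were not separated.

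With 3 libraries against 3, the 10 possible splits are too few for a test of chance. The real grouping called 4 genes for GSK343 against the knockout, 23 for GSK343 against the control, 2186 for GSK-J4 against the knockout and 1916 for GSK-J4 against the control, each with 0 as the highest of the other splits, so that 1 split reached the real count. Each knockout against its control called 0, as did every other split, so that 10 of 10 reached it. For the difference of the knockout effects 40 of 40 drawn splits reached the real count of 0.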
